A study of Mus musculus with 2 samples.

How the data were processed

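MicroRNA levels were measured in mouse ID-8 ovarian tumours with the Toray 3D-Gene miRNA array, on which total RNA labelled with the dye Cy5 is hybridised to 1 array per sample. There were 2 arrays, 1 from the control IgG group and 1 from the bevacizumab group. The submitters' texts differ on the RNA: the design text names tumour RNA and a standard RNeasy column, and the sample protocol names cells and a miRNeasy column, which is made to retain small RNA. They do not say whether an RNA came from 1 animal or from several, and they name no scan or hybridisation batch. With 1 array per group there is no spread between animals, no test between the groups was possible, and no p-value is given; every difference compares these 2 arrays.

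Per the file headers, each deposited scanner file gives a spot intensity (the spot median at 635 nm) and a local background intensity, from 3 scan gains related to one another by least squares. These intensities are linear, not background-corrected and not normalized. Each array had 3200 spots: 1900 miRNA probes, 896 blank spots and 404 control spots. No spot was marked as failed. Each miRNA probe had 1 spot, and 12 probes were assigned to several miRNAs, which are named together. The deposited value table is also in linear intensity units, not centred per miRNA. Its scale, set against the scanner values, was the spot intensity minus the mean of the array's blank spots, divided by a factor that gave the listed miRNAs of each array a median of 25.0; the largest departure from that line was 0.0265 intensity units on the control array and 0.0621 on the bevacizumab array. Dim miRNAs are empty in that table. The software that made the scanner files and the table is not given in the sources used here.

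A miRNA was called detected when its spot exceeded the mean plus 2 SD of the blank spots, after leaving out the highest and lowest 5% of them. The deposited table lists every miRNA so detected and 1 more per array. In the main setting, spot intensities were corrected with the normexp model of limma 3.58.1 in R 4.3.3, using the blank spots as negative controls and an offset of 50, and the 1900 miRNA probes were quantile-normalized between the arrays. The blank spots took the place of the local background because the local background exceeded the spot itself for 49 miRNA probes on the control array, the let-7 probes among them. Differences are log2 values, bevacizumab minus control. They are on a scale that includes the offset, so they understate the change of dim miRNAs, and quantile normalization makes them relative to the other miRNAs on the array. Counts used a fixed size of 2-fold among miRNAs detected on both arrays. For a miRNA detected on 1 array only, the fold is a lower bound against the higher of the other array's lowest detected level and the probe's own level there.

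The precision comes from control probes printed in 8 spots each. Of 6 such probes detected on both arrays, the 5 brightest were used (Spike Control 1, Spike Control 2, S-Probe26, S-Probe27 and S-Probe28), a choice made after their values were seen. Negative Control 3, at 5.91 and 14.2 units above the blanks, was left out; its blank-subtracted log2 signals had repeat-spot SDs of 0.22 and 0.57. For the 5, the spread of repeat spots implied an SD of 0.15 for a single log2 difference. This covers spot-to-spot error within these arrays only, not labelling, hybridisation or animals. The main setting was tested on simulated data for this comparison, with 1900 probes and 50 miRNAs planted per size and direction. Shares are of the planted miRNAs still detected on both arrays, which leaves out many planted losses. It called 93.9% of the miRNAs planted 16-fold higher (46 of 49) and 78.9% of those planted 16-fold lower (15 of 19). It called 42.0% of those planted 4-fold higher (21 of 50) and 30.0% of those planted 4-fold lower (9 of 30). It called 1 of 1125 unchanged miRNAs. The simulation built both arrays from the control array, with one common factor and a small chosen noise for every probe. In the real arrays the log2 ratios of the 22 control probes detected on both had an SD of 0.95. The simulated count of false calls therefore does not carry over to the real arrays. The median log2 difference found for a planted 16-fold loss was -1.77 with the offset of 50 and -4.02 with an offset of 0. A planted list of 9 miRNAs, all planted 16-fold lower, lay at percentile 0.0, which such a size could hardly miss. Of 40 random lists, 1 fell in the outer 5% of random draws. The changes were planted without regard to miRBase accession, so that share does not carry over to the real lists.

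The 17 miRNA lists (angiogenesis, hypoxia, tumour-related families, imprinted clusters, and markers of stromal, immune, erythroid, epithelial and neighbouring tissues), the size threshold, the normalizations to be tried and the rule for naming miRNAs were fixed before the data were examined. List members come from textbook knowledge of tissue and pathway expression, and 10 probes belong to more than 1 list. A list's median was set against 10000 random lists of the same size, matched on mean level in 10 bins, as a description of these arrays. A second draw, added after seeing the data, was matched on miRBase accession class (below 1000, between, 25000 and above) and on level in 4 bins per class; the early class has 122 miRNAs and includes the list members themselves. Lists with fewer than 3 members detected on both arrays have no percentile. The rule named the 12 miRNAs with the largest and the 12 with the smallest difference among those at or above the median level, at least 2-fold and with the same sign under every planned normalization (quantile, median, 75th percentile, cyclic loess and none). It also named the 5 brightest on each array, the 5 brightest detected on 1 array only, up to 4 members of each list (the brightest 2 and 2 with the largest differences), and miR-210-3p, miR-126a-3p, miR-143-3p and miR-145a-5p. Alternatives were subtraction of the blank mean, an offset of 0, scaling to the median or the 75th percentile, cyclic loess, no normalization, the deposited value table, other detection limits and other size thresholds. Scaling to the spike controls and a correction by local background were added after seeing the data. The spike scaling was applied to values with an offset of 0 and without quantile normalization. It therefore differs from the main setting by more than the scale factor. No genome was used here, so no coordinates are given. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.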

Results

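The experiment asked which miRNAs differ in ovarian tumours of mice that received bevacizumab, an antibody raised against the human angiogenic growth factor VEGF-A. The arrays do not measure whether it blocked the VEGF-A of these mice. C57BL/6 mice, 5 weeks old, were inoculated in the peritoneal cavity with luciferase-expressing ID-8 cells, a mouse ovarian cancer line. From day 14 they received either bevacizumab or control IgG, each at 5 mg/kg, 2 times a week, and tumours were taken at day 42. There was 1 array for each treatment, so all values below describe 1 control array and 1 bevacizumab array, with a repeat-spot SD of 0.15 for a log2 difference as the only measured error.

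The control array detected 1416 of 1900 miRNA probes (74.5%) and the bevacizumab array 940 (49.5%). Blank spots lay at 72.8 ± 0.828 intensity units on the control array and at 185 ± 4.03 on the bevacizumab array (trimmed mean ± SD over spots). The median detected miRNA was 12.6 units above the blanks on the control array and 30.5 units on the bevacizumab array. The 5 brightest miRNAs took 40.6% of the detected signal on the control array and 19.6% on the bevacizumab array. Both arrays detected 917 miRNAs, 499 were detected on the control array only and 23 on the bevacizumab array only. Across the 917 miRNAs, which are not independent replicates, normalized levels correlated with Pearson's r of 0.789 and Spearman's rho of 0.780.

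The stromal and mural, miR-29, miR-17-92, let-7 and both angiogenesis lists were lower on the bevacizumab array, and so were most bright miRNAs with early numbers in the miRBase catalogue (64 of 100 at least 2-fold lower). Of 94 list members detected on both arrays, counted once per list, 58 had such early numbers. In the lists just named the share was higher: 9 of 10 pro-angiogenic, 9 of 11 anti-angiogenic and 8 of 9 miR-17-92 members. It was 6 of 7 for the stromal and mural list, 3 of 3 for miR-29 and 9 of 9 for let-7. In the Dlk1-Dio3 and Sfmbt2 lists, which were not lower, it was 0 of 7 and 1 of 23. Against random lists matched on level alone, 6 of 11 list medians lay below the central 95%. Matched on catalogue class as well, a comparison added after seeing the data, only the miR-29 median did. The early class has 122 miRNAs and includes the list members, so that comparison leaves little room for a list to lie outside. With local background no list median was at least 2-fold lower. Of the 917 miRNAs, 106 were at least 2-fold lower and 96 at least 2-fold higher after quantile normalization (median of all 0.14), but 91 of the 96 were lower under scaling to the spike controls and 22 in the deposited table. Lower miRNAs made up 52.5% of these calls, 66.7% with median scaling, 67.9% with cyclic loess, 91.7% in the deposited table and 99.3% with spike scaling. They made up 47.5% at a detection limit of 5 SD, 35.9% with the blank mean subtracted and 33.8% with an offset of 0. With the blank mean subtracted and with an offset of 0 the lower calls rose to 156, but the higher calls rose more, to 278 and 306. Among the lower miRNAs, the largest difference was that of miR-1a-3p, a striated muscle miRNA, at 19.5-fold lower (log2 -4.28). It was followed by miR-143-3p, which is abundant in smooth muscle and mural cells, at 13.2-fold lower (log2 -3.72), and by miR-1983 at 10.3-fold lower. miR-126a-3p, the main endothelial miRNA, was 7.33-fold lower. The growth-related miR-21a-5p was 6.75-fold lower and the erythroid miR-451a 7.17-fold lower. miR-29b-3p and miR-29c-3p, which target collagen transcripts, were 7.39-fold and 6.37-fold lower, and let-7g-5p was 7.17-fold lower. miR-26b-5p, miR-30e-5p and miR-652-5p were lower by 6.32-fold, 6.25-fold and 6.18-fold. With an offset of 0 the log2 differences of miR-143-3p, miR-126a-3p and miR-21a-5p were -4.72, -3.62 and -2.85. The authors' deposited table has no offset and also scales the arrays by another factor, which lowers the bevacizumab array by 2.41-fold against the control array; there these miRNAs were 75.1-fold, 29.9-fold and 19.9-fold lower. The spot of miR-1a-3p on the bevacizumab array read 195 units against a detection limit of 193, so its fold is imprecise. That holds too for the other named miRNAs below the 5 SD limit on an array: miR-194-5p, miR-146a-5p, miR-146b-5p, miR-31-3p, miR-182-5p, miR-487b-3p, miR-669b-3p and miR-34b-3p. All 106 kept their sign under each planned normalization; a correction by local background, added after seeing the data, turned 44 of them, miR-1a-3p, miR-143-3p, miR-126a-3p, miR-21a-5p, let-7g-5p and miR-30e-5p among them.

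**Figure D1:**
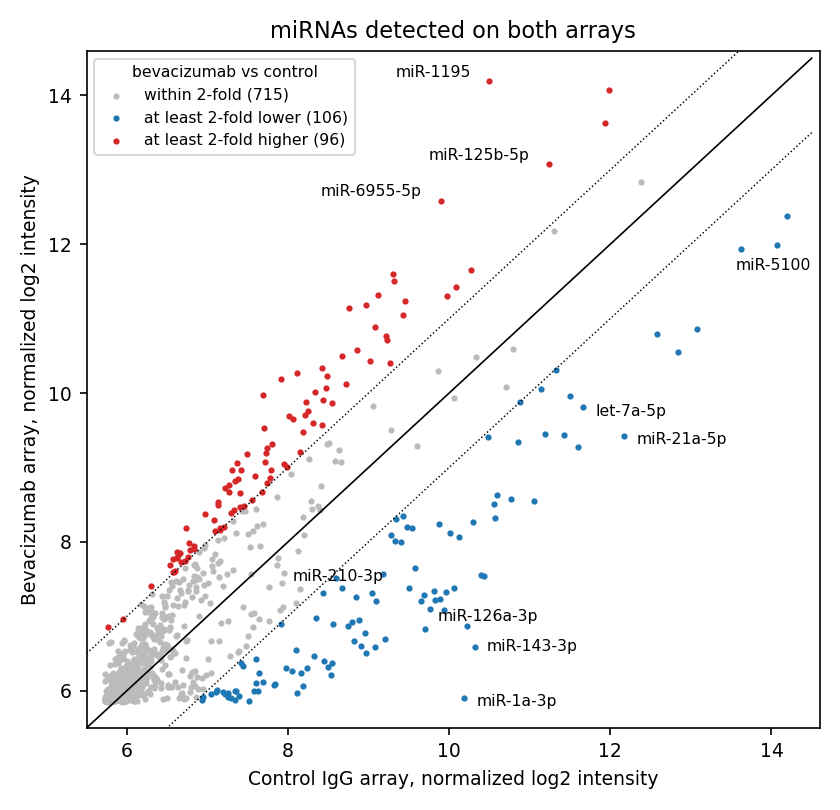
Normalized log2 intensity on the control IgG array (x axis) and on the bevacizumab array (y axis) for the 917 miRNAs detected on both, 1 point per miRNA. The solid line marks equality and the dotted lines a 2-fold difference; 106 miRNAs lie on or below the lower line and 96 on or above the upper one, though 91 of the 96 were lower on the bevacizumab array under spike scaling and 22 in the deposited table.

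A second set of miRNAs was higher relative to the rest, in directions that rest on the scaling. miR-1195 was 12.9-fold higher (log2 3.69), was the brightest miRNA of the bevacizumab array, and stayed above 0 in the authors' deposited table (2.24-fold) and under spike scaling (log2 0.13). miR-770-3p was 4.84-fold higher and miR-8113 4.83-fold, with log2 differences of 0.15 and 0.017 under spike scaling. miR-6955-5p was 6.41-fold higher, miR-6238 5.22-fold, miR-6988-5p 4.91-fold, miR-6937-5p 4.65-fold, miR-7063-5p 4.63-fold, miR-709 4.54-fold, miR-6236 4.46-fold and miR-677-3p 3.78-fold, and all of these were below 0 under spike scaling. miR-7005-5p, miR-125b-5p and miR-2137, 3 of the brightest on the bevacizumab array, were 4.26-fold, 3.57-fold and 3.22-fold higher after quantile normalization but lower in the deposited table (log2 -0.15, -0.26 and -0.35) and under spike scaling. The authors' deposited table has 27 miRNAs at least 2-fold higher and 298 at least 2-fold lower. miR-1902, also among the brightest on the bevacizumab array, was within 2-fold after quantile normalization (log2 0.45), but 2.62-fold lower in the deposited table and at log2 -2.42 under spike scaling. The brightest miRNAs of the control array were lower: miR-3968 by 3.50-fold, miR-5100 by 4.26-fold, miR-6366 by 3.22-fold, miR-3963 by 4.67-fold and miR-6412 by 4.87-fold. These folds follow quantile normalization, which gives both arrays the same set of values. As a group, the 5 brightest of either array can then not be higher on the other, so the choice set that direction. miR-5100 and miR-7005-5p swapped values (log2 -2.09 and 2.09), as did miR-6366 and miR-2137 (-1.69 and 1.69), and are not separate findings. In the deposited table, which scales each array by a factor, the 5 of the control array were 13.5-fold to 20.8-fold lower.

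Both angiogenesis lists were lower, the one named for promoting vessel growth as well as the one named for restraining it. Of 10 pro-angiogenic or hypoxia miRNAs detected on both arrays, 8 were at least 2-fold lower, with a median log2 difference of -1.85. miR-10b-5p was 5.61-fold lower, let-7f-5p 5.03-fold and miR-23b-3p 2.13-fold. The hypoxia-induced miR-210-3p differed by 1.29-fold (log2 -0.37), which is below the 2-fold size, but was 3.14-fold lower in the deposited table and at log2 -2.68 under spike scaling. miR-296-5p, picked out after its value was seen, was the only member at least 2-fold higher (log2 1.08), and was below 0 in the deposited table (-0.059) and under spike scaling (-1.09). Of 11 anti-angiogenic miRNAs, 9 were at least 2-fold lower and none higher, with a median of -1.89. In this list the miR-15/16 family members miR-195a-5p, miR-15a-5p, miR-322-5p and miR-16-5p were lower by 6.08-fold, 5.48-fold, 5.27-fold and 4.76-fold. The medians of the pro-angiogenic and anti-angiogenic lists lay at percentiles 0.56 and 0.01 of random lists matched on level, and at 31.6 and 3.72 of those matched on level and catalogue class. With local background the pro-angiogenic median was -0.47 and the anti-angiogenic 0.45.

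Proliferation-related and broadly expressed families were lower as well. In the miR-17-92 cluster and its paralogs, which are driven by MYC and E2F factors, 8 of 9 miRNAs were at least 2-fold lower (median -1.88, percentile 0.59). miR-19b-3p was 4.93-fold lower, miR-106a-5p 4.54-fold, miR-93-5p 3.32-fold and miR-106b-5p 3.00-fold. All 9 let-7 family probes were at least 2-fold lower (median -1.87), from let-7g-5p at 7.17-fold through let-7i-5p at 5.47-fold and let-7a-5p at 3.61-fold to let-7b-5p at 2.01-fold; their median lay at percentile 2.14. Members of let-7 differ by few bases, so signal can be shared between their probes. All 3 miR-29 miRNAs were lower, with a median of -2.67 at percentile 0.35, and miR-29a-3p was 5.67-fold lower. Of 5 miRNAs in the oncomiR list, 3 were at least 2-fold lower, miR-21a-5p, miR-221-3p (2.81-fold) and miR-31-3p (2.30-fold), while miR-31-5p was lower by 1.25-fold. The list median was -1.20, at percentile 4.80 of random lists matched on level and thus inside their central 95%; it was -0.91 at a detection limit of 5 SD and -0.32 with no detection filter. Matched on level and catalogue class, the miR-17-92, let-7, miR-29 and oncomiR medians lay at percentiles 19.6, 34.2, 2.02 and 20.4. With local background the medians of the miR-17-92 (0.63), let-7 (2.65) and oncomiR (0.33) lists were above 0 and that of miR-29 was -0.34.

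**Figure D2:**
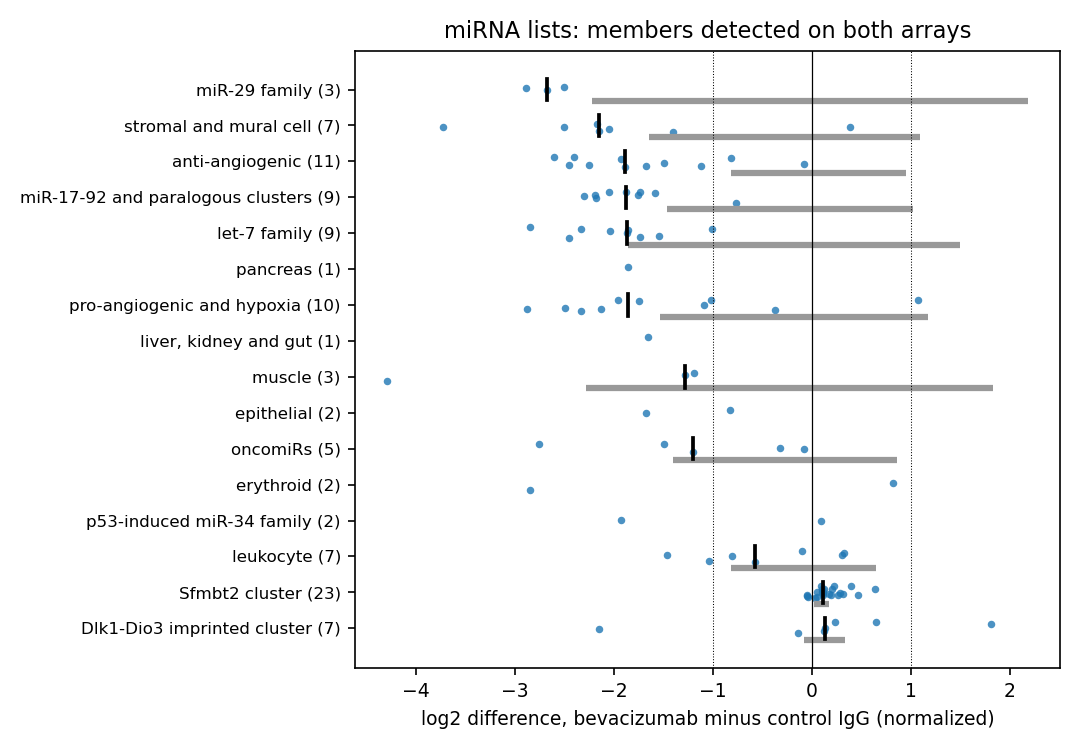
log2 difference, bevacizumab minus control IgG, of each list member detected on both arrays (blue points), with the number of such members in parentheses. Black bars are list medians and grey bars the central 95% of medians of 10000 random lists matched on level, both drawn for lists with at least 3 members; the miR-29, stromal, anti-angiogenic, miR-17-92, let-7 and pro-angiogenic medians lie to the left of their grey bars. Matched on catalogue class as well (not drawn), only the miR-29 median does.

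Stromal and mural cell miRNAs were lower, with 6 of 7 at least 2-fold lower and a median of -2.14 (percentile 0.095, or 5.76 when matched on catalogue class too). That median was -0.88 with local background, -4.62 in the deposited table and -5.67 with spike scaling. Besides miR-143-3p, the probe shared by miR-199a-3p and miR-199b-3p was 5.65-fold lower, miR-199b-5p 4.51-fold and miR-145a-5p 4.14-fold. miR-214-3p, picked out after its value was seen, was the member above 0 (log2 0.39), and was below 0 in the deposited table (-0.58). The 3 striated muscle miRNAs detected on both arrays were lower: miR-133a-3p and miR-133b-3p by 2.27-fold and 2.43-fold, less than miR-1a-3p; their median of -1.28 lay at percentile 22.5, and was 0.50 with local background. Of 7 leukocyte miRNAs, 2 were at least 2-fold lower, and the list median was -0.58 (percentile 6.71). They were miR-146b-5p at 2.75-fold and miR-146a-5p at 2.05-fold, whereas miR-181a-5p (log2 -0.10) and miR-342-3p (log2 0.30) were within 2-fold. In the deposited table these 4 miRNAs were at log2 -4.58, -3.95, -1.33 and -0.72. A further 3 were detected on the control array alone: miR-142a-3p, which is specific to blood cells, at least 2.82-fold lower, and, picked out after their values were seen, miR-142a-5p at least 2.08-fold lower and miR-155-5p, too dim for a bound. The leukocyte median was -2.63 in the deposited table and 0.10 at a detection limit of 5 SD, at which both miR-146 probes and miR-181b-5p drop out.

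Epithelial miRNAs were mostly not detected on the bevacizumab array, which also missed 499 of all 1416 probes detected on the control array. All 10 epithelial probes were detected on the control array and 2 of them on the bevacizumab array, miR-200b-3p (3.19-fold lower) and miR-182-5p (1.77-fold lower). Of the other 8, only miR-200a-3p and miR-429-3p (2.19-fold) had a bound of 2-fold or more. miR-205-5p and miR-183-5p were too dim for a bound, so their loss can reflect the detection limit alone. These last 3 were picked out after their values were seen. miR-200a-3p was the brightest miRNA of those seen on the control array alone, at least 3.99-fold lower. It was followed by the erythroid miR-144-3p at least 3.18-fold lower, miR-101a-3p at least 3.05-fold lower, miR-1839-3p at least 2.87-fold lower and miR-142a-3p. Of the 499, 15 had a bound of 2-fold or more. The 5 brightest of the 23 seen on the bevacizumab array alone were miR-188-3p, miR-291b-5p, miR-466l-3p, miR-7240-5p and miR-6988-3p, with bounds of at most 1.40-fold. In the erythroid list, miR-451a was lower while the probe shared by miR-486a-5p and miR-486b-5p was 1.77-fold higher (log2 -0.50 under spike scaling). In the miR-34 list, miR-34a-5p was 3.81-fold lower, miR-34b-3p was within 2-fold (log2 0.10) and miR-34b-5p was seen on the control array alone, at least 1.59-fold lower.

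The hepatocyte miRNA miR-122 (both arms), the acinar miR-216a-5p and the neuronal miR-124-3p were not detected on either array. The other 5 neural probes were detected on the control array alone. miR-216b-5p was detected on the control array but was too dim for a bound, and miR-9-5p and miR-128-3p had bounds of 1.39-fold and 1.05-fold. miR-148a-3p was 3.62-fold lower, miR-194-5p 3.14-fold lower (log2 -5.19 in the deposited table and 0.20 with local background), and miR-192-5p was at least 2.16-fold lower. The imprinted Dlk1-Dio3 and Sfmbt2 clusters were mostly within 2-fold in the main setting, with medians of 0.14 and 0.12 (percentiles 55.4 and 63.7). With the blank mean subtracted and no offset the medians were 1.02 and 0.63. Both were below 0 in the deposited table (-0.15 and -0.28) and under spike scaling (-1.19 and -1.31). Within Dlk1-Dio3, miR-487b-3p, below the 5 SD limit on the bevacizumab array, was 4.43-fold lower, and miR-494-3p was 3.51-fold higher (log2 -0.89 under spike scaling); miR-370-3p (log2 0.65) and miR-434-3p (log2 0.24) were within 2-fold (log2 -1.19 and -0.84 under spike scaling). None of the 23 Sfmbt2 cluster probes detected on both arrays differed by 2-fold in the main setting, including miR-669c-3p, miR-669b-3p, miR-466i-5p and miR-467g, which lay between 0.12 and 0.64. Of these 4, miR-669b-3p (log2 2.40, below the 5 SD limit) and miR-467g (log2 1.05) passed that size in the deposited table.

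Control probes differed from one another in their ratio between the arrays. Blank-subtracted signals of Spike Control 1, Spike Control 2, S-Probe26, S-Probe27 and S-Probe28 were 4.61 to 5.11 times as high on the bevacizumab array. These 5, each in 8 spots, were chosen after their values were seen, and some single-spot S-Probes were brighter than S-Probe26 and S-Probe27. The other 17 control probes detected on both arrays, Negative Control 3 and 16 S-Probes with 1 spot each, ranged from 0.589 to 5.58 times, with a median log2 ratio of 1.03. Of these 17, 16 lay below the lowest of the 5. The median of the 917 miRNAs was 1.77 times as high before normalization, and 885 of them lay below the lowest of the 5 control probes. The 96 miRNAs called higher after quantile normalization, of which 91 were lower under spike scaling, were 3.07 times as high (median, not normalized), and the 106 called lower were 6.72-fold lower in the same units. Spike scaling, added after seeing the data, gave 5 miRNAs at least 2-fold higher and 666 at least 2-fold lower. It has no offset, so part of the contrast with the main setting is not due to the spikes. An offset of 0 with quantile normalization gave 306 higher and 156 lower. The labels do not say at which step the control RNAs were added or what the S-Probes measure, and no replicate array separates treatment from the handling of the RNA.

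**Figure D3:**
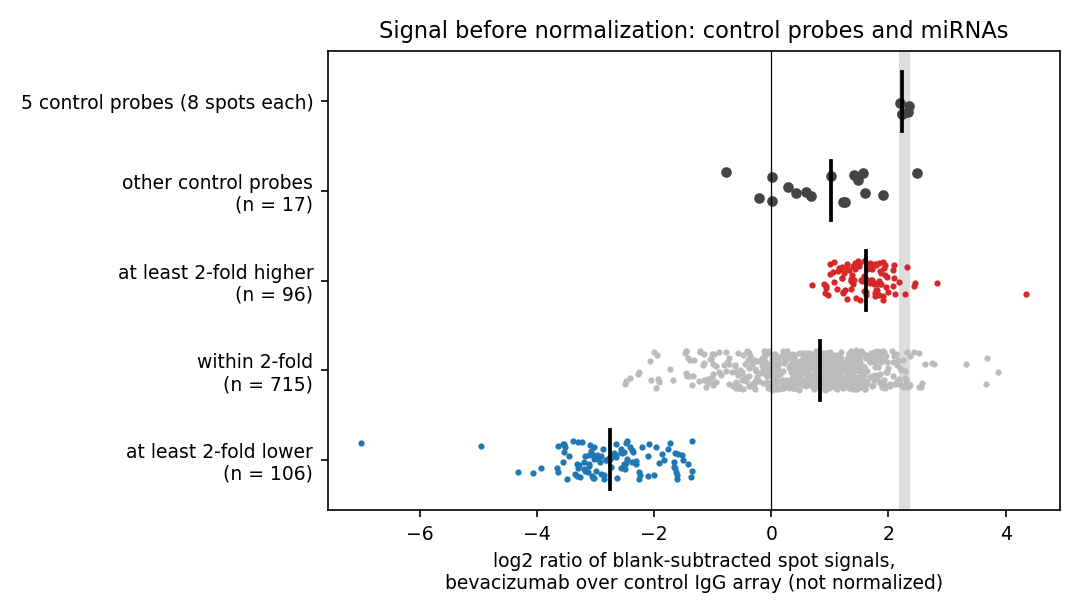
log2 ratio of blank-subtracted spot signals before normalization, bevacizumab over control IgG array, for 5 control probes (each a mean of 8 spots), for the 17 other control probes detected on both arrays and for miRNAs by their normalized difference. Black bars are medians and the grey band spans the 5 control probes; the miRNAs called higher have a median of 1.62 (91 of these 96 are lower under spike scaling) and those called lower a median of -2.75, both below the 5 control probes at 2.20 to 2.35, while the other control probes have a median of 1.03.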

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

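The 4 tests in this part were chosen only after the result was seen, and the one on a single factor replaced 2 earlier tests, on the spread of bright miRNAs and on median scaling, that could hardly have come out otherwise. The signals of 18 control probes, which are not part of the comparison of miRNAs, were above their level on the control array by over 0.15 on the log2 scale, the repeat-spot SD of bright probes, which understates the error of dim ones: Spike Control 1 was 5.11 times as high on the bevacizumab array, Spike Control 2 4.71 times, S-Probe26 4.61 times, S-Probe27 5.01 times and S-Probe28 4.71 times. These 5 are each a mean of 8 spots and were singled out after their values were seen; their log2 ratios had an SD of 0.065. Negative Control 3, also in 8 spots but dim, was 2.39 times as high. Among S-Probes with 1 spot each, the ratio was 1.60 for S-Probe1003, 2.78 for S-Probe1005, 1.21 for S-Probe1007, 2.97 for S-Probe1010, 5.58 for S-Probe1011, 1.34 for S-Probe1013, 1.504 for S-Probe1014, 2.66 for S-Probe1016, 3.05 for S-Probe1017, 2.04 for S-Probe1018, 2.33 for S-Probe1019 and 3.75 for S-Probe1021. Of the other 4 S-Probes detected on both arrays, S-Probe1004 and S-Probe1020 were each 1.01 times as high and S-Probe1002 and S-Probe1022 were lower (0.589 and 0.867 times). Negative Control 3, S-Probe1010, S-Probe1011, S-Probe1013 and S-Probe1017 were below the 5 SD limit on an array, so their ratios are imprecise. Over all 22 control probes the SD was 0.95, and what the S-Probes measure is not stated.

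The first pattern weighed is the set of 106 miRNAs at least 2-fold lower on the bevacizumab array. A single factor between the arrays, from the amount of RNA, labelling or scanner gain, acts alike on every miRNA. Of 11 lists fixed before the data, 6 (54.5%) had medians outside the central 95% of random lists matched on level. That argues against such a factor alone, but matched on catalogue class as well, only 1 list lay outside. The early class has 122 miRNAs and includes the list members themselves, so this match leaves little room for a list to lie outside. For let-7 its central 95% ran from -2.25 to -1.01. It cannot tell whether the lists differ from other miRNAs with early catalogue numbers. The 6 lists therefore do not count as separate support. A brightness-dependent trend could not be judged from cyclic loess, after which 102 of the 106 (96.2%) stayed at least 2-fold lower. The 106 were called after quantile normalization, which already removes most of such a trend, so little else could result. Without normalization 102 stayed as well, and with local background 37 did. Whether fewer stromal, mural and endothelial cells were the whole cause could not be decided. The miR-17-92 list had a median of -1.88 with an SD of 0.46 among members (0.63 with local background, which exceeded the spot on 49 probes). Matched on level and catalogue class, that median lay at percentile 19.6. Dividing cells of every type express this list, stromal and endothelial ones included, so losing such cells could lower it too. Loss or breakdown of small RNA during extraction that affects some miRNAs more than others, and the treatment itself, stay open as well. Each treatment has 1 array, and the submitters' texts name different extraction columns.

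The second pattern is the set of 96 miRNAs at least 2-fold higher, 91 of which were lower under spike scaling. Their median log2 ratio before normalization was 1.62, below the highest of the 5 control probes at 2.35, and 4 of the 96 exceeded that probe. But the other 17 control probes had a median of 1.03, below the 1.62 of these miRNAs. Of these 17, 16 are S-Probes with 1 spot each, and what they measure is not stated. Their spread therefore cannot decide whether the bevacizumab array had one gain. The log2 ratios of the 5 alone had an SD of 0.065. One gain alone could not set these miRNAs above the others, since normalization removes it. Whether they rose in themselves, or others lost signal while an overall gain lifted all, stays open.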

How the results depend on the processing

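Spike scaling, the local background correction and random lists matched on accession class were chosen only after the result was seen. Of the 106 miRNAs lower by at least 2-fold, all stayed so under blank subtraction, an offset of 0, median and 75th percentile scaling, the deposited table, no detection filter and spike scaling, 102 did under cyclic loess and without normalization and 37 with local background; at a detection limit of 5 SD 86 were still tested and lower. Of the 96 higher by at least 2-fold, all stayed so under blank subtraction, an offset of 0 and no detection filter, 95 at 5 SD, 81 without normalization, 66 with 75th percentile scaling, 59 with cyclic loess, 55 with median scaling, 26 with local background, 6 in the deposited table (22 were lower there) and 1 with spike scaling (91 were lower). The count of miRNAs at least 2-fold higher was 278 with the blank mean subtracted, 306 with an offset of 0, 55 with median scaling, 61 with cyclic loess, 27 in the deposited table, 48 with local background and 5 with spike scaling, and it was 178 at a 1.5-fold and 29 at a 3-fold threshold. The count at least 2-fold lower was 298 in the deposited table, 48 with local background, 666 with spike scaling and 67 at a 3-fold threshold. It was 156 both with the blank mean subtracted and with an offset of 0. Counts changed with the threshold by construction; for the scalings the cause was not tested, but the median of all miRNAs moved from 0.14 to 0.57, 0.60, 0.02, 0.05, -0.45, 0.01 and -1.49 under the 7 settings named first. The share of calls that were lower moved from 52.5% to 35.9% with blank subtraction, 33.8% with an offset of 0, 66.7% with median scaling, 67.9% with cyclic loess, 91.7% in the deposited table and 99.3% with spike scaling; it was 47.5% at 5 SD and 50% with local background. miRNAs seen on the bevacizumab array alone numbered 7 at 5 SD, against 23. Pearson's r between the arrays was 0.830 with no detection filter, which adds dim probes. Lists with a median at least 2-fold lower numbered 8 of 11, between 6 and 11 under all alternatives except local background, which left 0. Lists below the 2.5th percentile of random lists numbered 6 with lists matched on level, 9 without matching and 1 with lists matched on level and accession class.

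Counting only named miRNAs at least 2-fold different in the main setting, spike scaling turned the sign of 12: miR-677-3p (-0.59), miR-6236 (-0.22), miR-709 (-0.40), miR-7063-5p (-0.43), miR-6937-5p (-0.36), miR-6988-5p (-0.22), miR-6238 (-0.19), miR-6955-5p (-0.019), miR-7005-5p (-1.18), miR-2137 (-1.38), miR-125b-5p (-1.30) and miR-494-3p (-0.89). The deposited table turned miR-7005-5p (-0.15), miR-2137 (-0.35) and miR-125b-5p (-0.26). The local background correction turned the medians of the anti-angiogenic (0.45), miR-17-92 (0.63), muscle (0.50), let-7 (2.65) and oncomiR (0.33) lists. It also turned miR-30e-5p (0.35), let-7g-5p (0.24), miR-1a-3p (0.50), miR-21a-5p (2.65), miR-126a-3p (0.66), miR-143-3p (0.55), miR-195a-5p (1.17), miR-15a-5p (0.48), miR-322-5p (1.07), miR-16-5p (1.48), miR-200b-3p (0.38), let-7i-5p (0.96), let-7a-5p (3.22), let-7b-5p (3.55), miR-194-5p (0.20), miR-19b-3p (0.63), miR-93-5p (1.18), miR-106b-5p (0.98), miR-29a-3p (1.64), miR-133a-3p (0.94), miR-221-3p (0.33), miR-31-3p (0.067), miR-148a-3p (0.012), miR-10b-5p (0.85) and let-7f-5p (2.80). The local background exceeded the spot for 49 miRNA probes on the control array and 22 on the bevacizumab array. Of 816 values of named miRNAs under alternatives, 298 stayed within the repeat-spot SD, 478 moved by more and 40 turned, the last again only for miRNAs at least 2-fold different; smaller ones that changed sign are among the others. Whatever the size, the sign of 75 named miRNAs detected on both arrays changed for 9 in the deposited table, 20 with spike scaling and 31 with local background. At 5 SD miR-1a-3p was no longer detected on both arrays, so the muscle list has no median there. No paired analysis was possible because each group has 1 array, and for the same reason no array could be left out. Precision is limited by 1 array per group and by the bevacizumab array's blank spread of 4.03 units against 0.828.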

Other observations

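Of the tests in this part, the one on hairpin arms was set before its result was seen, and the one on accession numbers was chosen after. miRNAs with an early number in the miRBase catalogue, whose accession numbers grow with time, stood apart from the rest. Among miRNAs at or above the median level, 64 of 100 with an early accession number (below 1000) were at least 2-fold lower and 3 were at least 2-fold higher. Among 160 with a number between the early and late classes, 27 were at least 2-fold lower and 42 at least 2-fold higher after quantile normalization; under spike scaling 91 of all 96 higher miRNAs were lower, and 22 were in the deposited table. Among 199 with a late number (25000 and above), 15 were at least 2-fold lower and 51 at least 2-fold higher, with the same dependence on the scaling (91 and 22 of all 96 lower). The share at least 2-fold higher was larger by 22.6 percentage points among late than early entries, and the share at least 2-fold lower was smaller by 56.5 points, but the middle class had about the same share higher as the late one. The comparison was drawn from values already seen, so it supports no explanation. Probe sequences were not analysed here, so base composition was not examined.

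The hypothesis that the differences follow the hairpin was tested on 209 hairpins with both arms detected on both arrays. If transcription or decay of the precursor set the differences, the 5p and 3p arms should move together. Spearman's correlation across hairpins was -0.032 (Pearson 0.13), below the 95th percentile of 0.0999 from 10000 random pairings matched on level, so the prediction was not met. Among 42 hairpins with both arms at or above the median level, Spearman's correlation was -0.012 (Pearson 0.22), with no random pairings drawn for them. Of these, 4 hairpins had both arms at least 2-fold lower. Another 4 had 1 arm at least 2-fold higher and the other at least 2-fold lower. After quantile normalization the 5p arm was at least 2-fold higher in 42 of the 209 hairpins and the 3p arm in 6, directions that spike scaling turns for most higher miRNAs. The 5p arm was at least 2-fold lower in 16 hairpins and the 3p arm in 13.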
